A study of Pleurotus ostreatus with 9 samples.

How the data were processed

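Poly(A) RNA of 9 shaken cultures of Pleurotus ostreatus strain GEMB-PO1 was measured by RNA sequencing, in 3 groups of 3 that the series design calls biological replicates. Per the labels' protocols, cultures grew in glucose, yeast extract and peptone medium (20, 5 and 5 g/L) at 28 °C and 180 rpm and were harvested on day 3. RNA was extracted with TRIzol, RNA with an integrity number of at least 7 was used, and strand-marked (dUTP) libraries of about 300 bp were made with 8 PCR cycles and read as 150 bp pairs on an Illumina NovaSeq. The control is described as having no chemical added, and no vehicle is named. The 2 label fields that give the BBP dose differ (50 and 200 mg/L). All libraries carry the same batch label, so no batch could be compared. No library with PB and no BBP was analysed here.

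Per the submitters' processing notes, fastp, HISAT2 and StringTie were used by the authors before deposit, with versions not given in the sources used here. Raw read counts per gene were made by the authors and are whole numbers in the deposited table; the counting tool, its strand setting, the genome build and the annotation version are not given in the sources used here. FPKM values per gene stand beside the counts in the deposited table and were also made by the authors. The deposited table has 10682 genes (10623 mRNA and 59 tRNA), each with a count in at least 1 library, and all of its per-sample columns were matched to a sample by name. Gene products are given as its annotation columns describe them: 10001 descriptions read hypothetical protein, 612 are informative, and 6188 genes have an ontology term, 3062 a KEGG pathway and 1951 an enzyme number. Enzyme or orthology numbers disagree with the description or ontology terms for some genes, so a product name is an annotation and not a measured activity. None of the identifiers matched the reference table of assembly ASM1446616v1 (11849 genes, 0 matched), so it was not used. Positions were not used here because the build is not given.

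Total counts per library ran from 38098599 to 49161706. A floor of 3 counts in a library, the most that a count of 0 allows, was used for genes with no counts; it covers counting error only, since reads copied by PCR are not independent molecules. Same-group libraries differed by far more than sampling noise (chi-square per degree of freedom 41.7 to 336.6), so no pair was treated as 1 library; this comparison cannot tell a second library of the same culture from one of another.

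The design written before the data were examined named limma on log2(FPKM + 1) unless the file held raw counts, in which case edgeR's quasi-likelihood test was to be used. The file held both, and the counts were tested. Genes with a mean FPKM of at least 1 over the 9 libraries were kept (9399). Counts were scaled by TMM factors, and 1 model with 3 groups was fitted to all 9 libraries with edgeR 4.0.16 (limma 3.58.1, R 4.3.3), so that the groups share 1 estimate of the spread. The common biological coefficient of variation was 0.201. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, 2-sided, in each of the 3 comparisons. SE was computed from the log2 change and the F statistic. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Principal components were computed on log2(FPKM + 1) with a pseudocount of 1.

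Gene lists were tested with limma's camera at a preset correlation of 0.01, and again with an estimated correlation, under which no list and no term was called. Before the data were examined 31 lists were fixed by words in the gene descriptions, and 7 had at least 5 tested members while 15 had none, because most descriptions are uninformative. Another 36 lists were built from the ontology, KEGG and enzyme columns after these columns were read and before any fold change was computed, and 34 had at least 5 tested members. The P450-type, peroxisome, fatty acid, glutathione, ribosome, proteasome and transporter lists are of this second kind. The 123 tests of 41 lists were adjusted together. Ontology terms (480) and KEGG pathways (99) with 10 to 300 tested members were tested in the same way, adjusted within each collection and comparison.

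Genes were named by a rule: in each comparison the 6 largest rises and 6 largest falls with an informative description, among genes called, with no overlap between libraries and a mean of at least 5 FPKM in the higher group, up to 2 called members of each list, or its most expressed member where none was called, and the CYP51 and P450 reductase genes. The rule was widened, before any fold change was computed, by the 5 largest rises and falls with an enzyme number and by members of the added lists, giving 180 named genes.

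The test was tried on simulated counts for the 9399 genes, with 50 genes changed at each of 4 sizes. At a log2 change of 0.5, 1, 2 and 3 it recovered 2, 35, 49 and 50 genes for BBP against control, 5, 29, 48 and 50 for BBP with PB against BBP, and 1, 29, 49 and 49 for BBP with PB against control. False calls were 5.41, 1.42 and 2.99% of the calls, in the same order. In these simulations changes of 0.5 were mostly not recovered. They held far fewer changed genes, with 134 to 148 calls per comparison against 1730 to 3865 in the data. Fewer changed genes make the adjusted p stricter, so these shares do not carry over to the real comparisons.

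The alternatives were other pseudocounts, filters, thresholds and scalings, limma on log2(FPKM + 0.1), quality weights, a robust variance model, each comparison from its own 6 libraries, the replicate number as a block, and each library left out in turn. Added after seeing the data were DESeq2 1.42.0, limma on log2(FPKM + 1), scaling by library size alone, camera on log2(FPKM + 1), and a fit without both BBP replicate 2 and control replicate 3. Random groupings and simulations (20 per overlap) used fixed seeds.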

Results

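The mycelium of the oyster mushroom Pleurotus ostreatus, a white-rot fungus, was profiled by poly(A) RNA sequencing in 9 shaken liquid cultures of strain GEMB-PO1. The cultures formed 3 groups of 3 biological replicates, harvested after 3 days. The control group had no chemical added. The BBP group received butyl benzyl phthalate, a phthalate ester used as a plasticizer. The third group received the same BBP together with 1 mM piperonyl butoxide (PB), an inhibitor of cytochrome P450 monooxygenases, and its libraries are called PB replicates 1 to 3. The BBP dose is given as 50 mg/L in the series design and as 200 mg/L in the sample protocols, so no dose is attached to the results. No culture with PB alone was analysed here. Total counts per library ranged from 38098599 to 49161706, and 9399 genes were tested. Expression is given as mean FPKM ± SD over the 3 libraries of a group, and changes as log2 fold change ± SE with the Benjamini-Hochberg adjusted p of edgeR's quasi-likelihood test.

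The first principal component of log2(FPKM + 1) held 61.3% of the variance and ordered the groups from control, at 35.97 to 40.99, through BBP, at -5.703 to 9.591, to BBP with PB, at -43.87 to -42.41. The second component held 13.8% and set the BBP libraries, at -26.31 to -20.3, apart from the other 6, at 7.697 to 16.25. The third component held 9.66% and spread the 3 control libraries from -27.65 to 24.96. BBP replicate 2 lay closest to the libraries with PB on the first component.

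**Figure D1:**
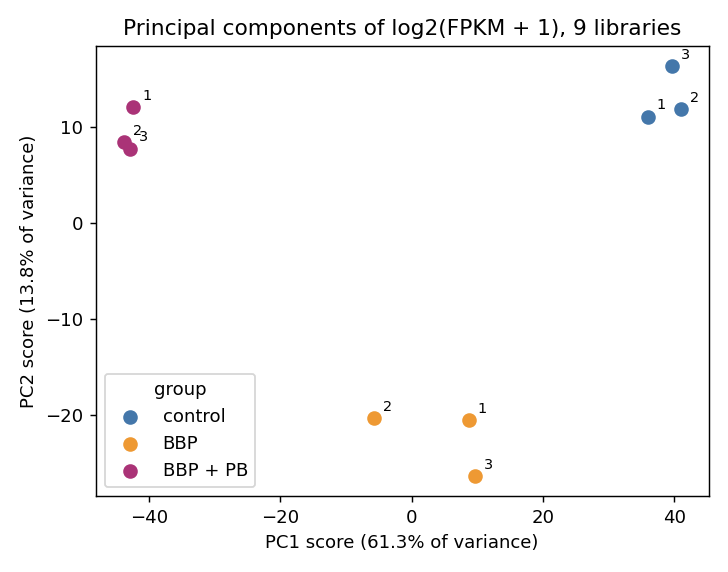
Scores of the 9 libraries on the first and second principal components of log2(FPKM + 1), with each point 1 library and colour giving the group. The first component runs from control at 35.97 or above to BBP with PB at -42.41 or below, and the BBP libraries lie between them with second component scores of -20.3 or below.

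The comparison of BBP with control asked which genes respond to the plasticizer. Among the genes named, the alcohol oxidase gene PLEOSDRAFT_1110004 (EC 1.1.3.13), whose enzyme class turns short alcohols into aldehydes and hydrogen peroxide, rose from 0.32 ± 0.0875 to 21.3 ± 10.9 FPKM (log2 change 6.12 ± 0.471, adjusted p = 0.000136). The P450-type monooxygenase gene PLEOSDRAFT_1032080 rose from 24.6 ± 6.12 to 799.9 ± 347 FPKM (5.15 ± 0.377, adjusted p = 0.000107), and a second one, PLEOSDRAFT_1047061, rose from 1.06 ± 0.0292 to 12.8 ± 5.15 FPKM (3.69 ± 0.351, adjusted p = 0.000307). Catalase, PLEOSDRAFT_1090819, which breaks down hydrogen peroxide, rose from 219 ± 41.4 to 649 ± 241 FPKM (1.67 ± 0.283, adjusted p = 0.00427). The hydrophobin Vmh2, PLEOSDRAFT_1091049, a small surface protein of vegetative hyphae, fell from 675 ± 148 to 60.3 ± 46.3 FPKM (-3.37 ± 0.697, adjusted p = 0.0104), and by -3.97 without BBP replicate 1.

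Genes of the peroxisome, a site of fungal fatty acid oxidation, were mostly higher with BBP. Of 70 tested members of that KEGG pathway 37 rose and 1 fell, with a median log2 change of 0.50 (camera adjusted p = 1.5e-12; adjusted p = 0.085 with an estimated correlation). They included PLEOSDRAFT_33522, annotated as a peroxisomal membrane carrier, at 66.6 ± 7.87 FPKM in control and 303 ± 42.8 with BBP (2.30 ± 0.138), and the long-chain acyl-CoA ligase genes PLEOSDRAFT_37195 (1.51 ± 0.13) and PLEOSDRAFT_1068548 (1.90 ± 0.363). In the fatty acid degradation pathway 20 of 49 rose and 0 fell (adjusted p = 1.17e-07; adjusted p = 0.085 with an estimated correlation). In glycolysis and gluconeogenesis 18 of 57 rose and 1 fell (adjusted p = 0.000271; adjusted p = 0.424 with an estimated correlation), or 14 and 3 with library size as the sole scaling. The gene for phosphoenolpyruvate carboxykinase, PLEOSDRAFT_1089535, which commits carbon to gluconeogenesis, rose from 4021 ± 406 to 8238 ± 424 FPKM (1.13 ± 0.149, adjusted p = 0.00142). Of 21 aldehyde dehydrogenase genes 4 rose and 0 fell (adjusted p = 0.00378; adjusted p = 0.387 with an estimated correlation), among them PLEOSDRAFT_171939 (2.08 ± 0.415). The succinate-semialdehyde dehydrogenase gene PLEOSDRAFT_1052335 rose from 22.6 ± 5.54 to 120.6 ± 31.9 FPKM (2.52 ± 0.222), formate dehydrogenase PLEOSDRAFT_1071241 from 132 ± 59.2 to 463 ± 5.39 FPKM (1.88 ± 0.318), and the mitochondrial alternative oxidase PLEOSDRAFT_1106868 from 156 ± 36.2 to 359 ± 27.3 FPKM (1.29 ± 0.219).

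Among genes of foreign-compound metabolism, 15 of 89 P450-type monooxygenase genes rose and 5 fell, and the list as a whole was not called (camera adjusted p = 0.0543). In the overlapping list annotated with monooxygenase activity 12 of 40 rose and 0 fell (adjusted p = 4.04e-06; adjusted p = 0.085 with an estimated correlation). The sterol 14-alpha-demethylase gene PLEOSDRAFT_1035254 (CYP51, the P450 of ergosterol synthesis) rose by 0.90 ± 0.198 (adjusted p = 0.0134), a call lost without control replicate 2 (adjusted p = 0.0511), and its copies PLEOSDRAFT_1061968 (0.31 ± 0.12) and PLEOSDRAFT_1047295 (-0.02 ± 0.187) were not called. Of 12 glutathione transferase genes, which conjugate electrophiles, 5 rose and 0 fell (adjusted p = 0.00267; adjusted p = 0.39 with an estimated correlation), with PLEOSDRAFT_1113463 going from 296 ± 66.6 to 929 ± 337 FPKM (1.76 ± 0.265). In the wider glutathione metabolism pathway 9 of 34 rose and 2 fell (adjusted p = 0.0109; adjusted p = 0.339 with an estimated correlation). Of 32 ABC transporter genes 8 rose and 3 fell (adjusted p = 0.0409; adjusted p = 0.255 with an estimated correlation), and PLEOSDRAFT_1056093 rose from 10.01 ± 1.96 to 52.2 ± 8.4 FPKM (2.495 ± 0.157). Of 43 genes with transmembrane transporter activity 8 rose and 1 fell (adjusted p = 0.0421; adjusted p = 0.599 with an estimated correlation). With library size as the sole scaling and on the TPM scale 5 of them rose and 1 fell, and 4 and 1 with limma on log2(FPKM + 1). On log2(FPKM + 1) values the ABC list was not called (camera adjusted p = 0.0825). Its call was also lost without control replicate 3 (adjusted p = 0.0809), BBP replicate 1 (adjusted p = 0.0689) or BBP replicate 3 (adjusted p = 0.101), and the transporter call without control replicate 1 (0.115) or 2 (0.0601) or BBP replicate 1 (0.0506) or 3 (0.185).

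At the preset correlation gene sets of ribosome assembly were called lower with BBP, and 2 of them are described below. The ontology terms snoRNA binding (0 rose and 12 fell of 19, adjusted p = 1.8e-06) and nucleolus (6 and 36 of 147, adjusted p = 5.49e-06) were also called lower. With an estimated correlation the adjusted p was 0.684 for both terms. In the small-subunit processome, the particle that matures the small ribosomal subunit, 21 of 40 genes fell and 1 rose (median -0.62, adjusted p = 1.69e-07 over 480 ontology terms; adjusted p = 0.684 with an estimated correlation). In the KEGG ribosome biogenesis pathway 27 of 93 fell and 7 rose (adjusted p = 0.0409; adjusted p = 0.713 with an estimated correlation). Those that rose included PLEOSDRAFT_1076619 (2.69 ± 0.222) and PLEOSDRAFT_1101897 (2.52 ± 0.236), the first of which is also annotated with monooxygenase activity. Structural genes of the ribosome, 8 higher and 14 lower of 149 (median -0.16, adjusted p = 0.0311; adjusted p = 0.784 with an estimated correlation), of the mitochondrial ribosome, 0 higher and 5 lower of 41 (adjusted p = 0.0185; adjusted p = 0.664 with an estimated correlation), and of the proteasome, 0 higher and 2 lower of 44 (adjusted p = 0.0197; adjusted p = 0.784 with an estimated correlation), were called lower as lists. On the TPM scale, and with library size as the sole scaling, 8 mitochondrial ribosome and 5 proteasome genes fell, and the median of the structural genes was -0.27. The 2 proteasome genes were PLEOSDRAFT_1060814 (-0.63 ± 0.158) and PLEOSDRAFT_1083621 (-0.33 ± 0.0972). The first call was lost without BBP replicate 1 (adjusted p = 0.0506) or 2 (adjusted p = 0.0646), and the second without any 1 of the 9 libraries (adjusted p = 0.0529 to 0.114). On log2(FPKM + 1) values ribosome biogenesis was not called (camera adjusted p = 0.0589). Without control replicate 3 the adjusted p became 0.298 for ribosome biogenesis, 0.0995 for the ribosome, 0.0636 for the mitochondrial ribosome and 0.498 for the proteasome, and without BBP replicate 3 it became 0.114, 0.327 and 0.0547 for the first 3. The ribosome call was also lost without control replicate 1 (adjusted p = 0.063), and the biogenesis and proteasome calls without BBP replicate 2 (adjusted p = 0.0502 and 0.0664).

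In the lists fixed by words in the gene descriptions, 0 of 15 hydrophobin genes rose and 4 fell, against 1 and 4 when adjusted over the list alone, and the list was not called (camera adjusted p = 0.358, direction lower, against a median of 0.05). Under quantile scaling 2 rose and 4 fell, and the median was -0.21, or -0.05 with library size as the sole scaling. Besides Vmh2 the falls included hydrophobin 3, PLEOSDRAFT_1114379, from 68.1 ± 38.2 to 12.4 ± 1.39 FPKM (-2.31 ± 0.353), and PLEOSDRAFT_1060612, from 542 ± 202 to 178 ± 64.5 FPKM (-1.49 ± 0.324). Of 209 carbohydrate-active genes 20 rose and 14 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.525), and 11 rose and 16 fell when only library size was used for scaling. Of 28 esterases and lipases 4 rose and 2 fell, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.318). Of 11 ligninolytic and dye peroxidases only the versatile peroxidase PLEOSDRAFT_156336 rose (0.77 ± 0.188), a call lost without BBP replicate 3 (adjusted p = 0.0647), and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.653), while 1 fell with library size as the sole scaling. Of 10 laccase genes 0 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.618). These were PLEOSDRAFT_1113032 (-0.80 ± 0.234) and PLEOSDRAFT_51622 (-0.90 ± 0.266). The first call was lost in every fit without 1 library but those without control replicate 2 or BBP replicate 3 (adjusted p = 0.0516 to 0.109), and the second in every one but that without control replicate 3 (adjusted p = 0.0619 to 0.145). The list median was 0.52, so the called members went against it. None of the 39 oxidative phosphorylation genes or the 6 mating type genes was called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.243 and 0.484). Under quantile scaling 3 oxidative phosphorylation genes fell, and 1 with library size as the sole scaling. On log2(FPKM + 1) values that list was called lower (camera adjusted p = 0.0196). In the wider KEGG oxidative phosphorylation pathway 5 of 86 genes rose and 2 fell, or 3 and 4 with library size as the sole scaling. Other named falls were the flammutoxin-like gene PLEOSDRAFT_168572 (-1.64 ± 0.255) and the plant-expansin-like gene PLEOSDRAFT_1045423, from 93.2 ± 63.6 to 19.6 ± 2.16 FPKM (-2.11 ± 0.36, and -1.46 without control replicate 3).

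In all, 1730 genes changed with BBP, 947 higher and 783 lower, of which 320 and 223 changed by at least 1 log2 unit. In 34.3% of tested genes the FPKM values of the 3 BBP libraries did not overlap those of the 3 controls. Libraries alike in everything, scaling included, would give 10%. FPKM follow total counts and not the TMM factors, so part of the excess may come from scaling. With library size as the sole scaling the split moved to 684 higher and 1108 lower, and the median change over all genes moved by -0.11. Without control replicate 2 the count was 967, with 584 higher and 383 lower, and the lower count was 480 without BBP replicate 1 and 512 without BBP replicate 2.

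**Figure D2:**
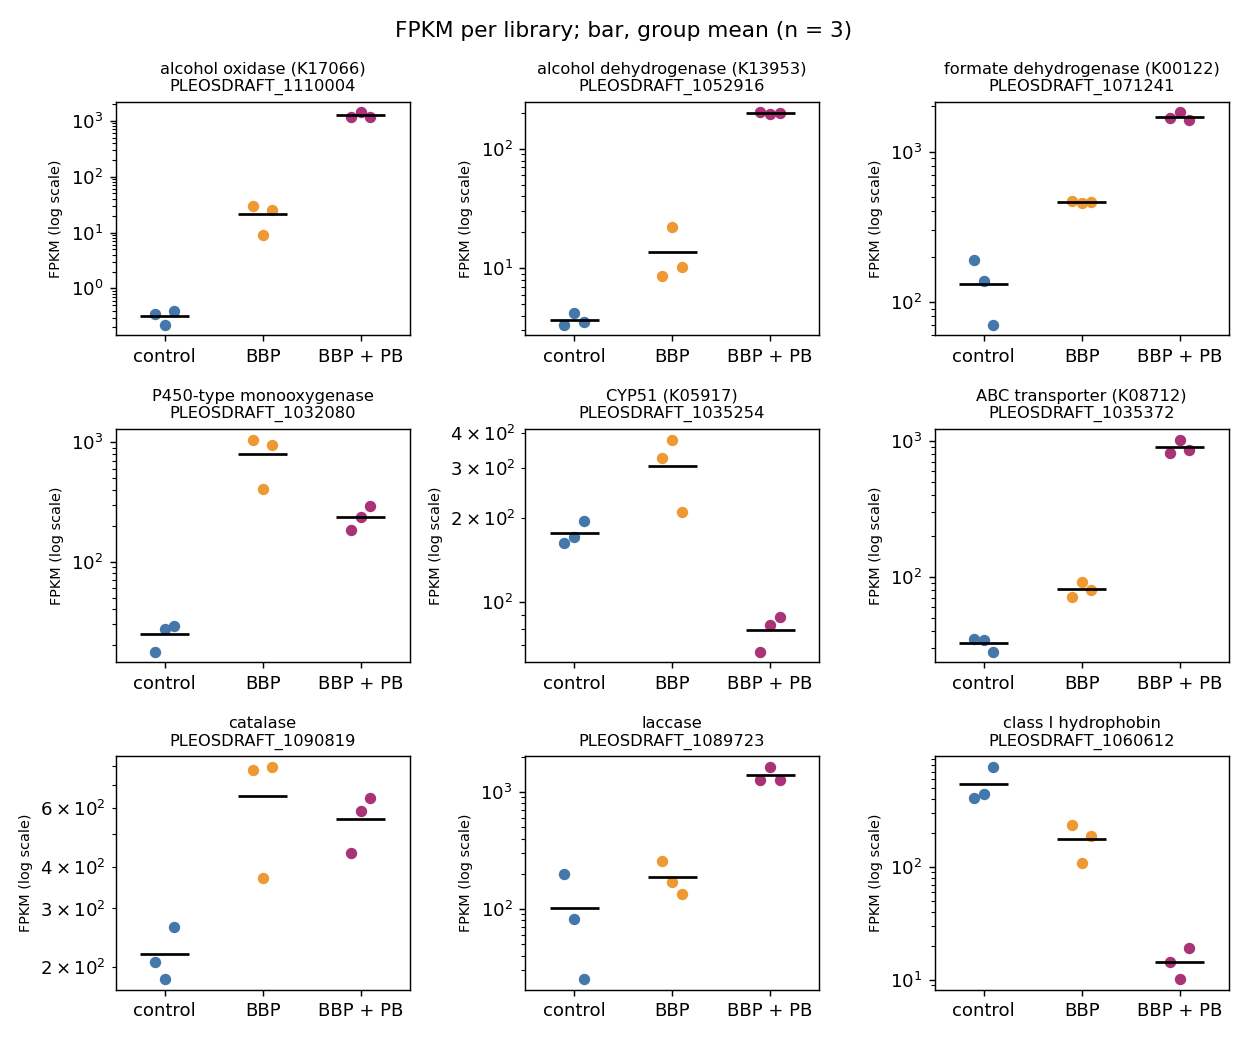
FPKM of 9 genes on log axes in the 9 libraries, with each point 1 library and the bar the group mean (n = 3). The alcohol oxidase gene rises from a mean of 0.32 FPKM in control to 21.3 with BBP and 1246 with BBP and PB, and the class I hydrophobin PLEOSDRAFT_1060612 falls from 542 to 178 and 14.6.

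The comparison of BBP with PB against BBP asked what the P450 inhibitor changes in BBP-treated mycelium. The ABC transporter gene PLEOSDRAFT_1035372 (KEGG orthology K08712, a family of drug efflux pumps) rose from 81.4 ± 10.6 to 896 ± 108 FPKM (3.56 ± 0.182, adjusted p = 6.01e-06). The alcohol oxidase gene PLEOSDRAFT_1110004 rose further, from 21.3 ± 10.9 to 1246 ± 140 FPKM (5.97 ± 0.441, adjusted p = 5.26e-05), as did the alcohol dehydrogenase gene PLEOSDRAFT_1052916, from 13.6 ± 7.34 to 200.4 ± 2.7 FPKM (3.98 ± 0.32, adjusted p = 7.51e-05). Agmatinase, PLEOSDRAFT_1065795, which forms putrescine, rose from 13.6 ± 1.18 to 193 ± 8.39 FPKM (3.93 ± 0.124, adjusted p = 2.63e-07). Vmh2, PLEOSDRAFT_1091049, fell from 60.3 ± 46.3 to 0.426 ± 0.391 FPKM (-6.96 ± 0.946, adjusted p = 0.00103; -6.36 without BBP replicate 1 and -7.76 without PB replicate 1).

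The P450-type monooxygenase genes, the class the inhibitor targets, went both ways, with 11 of 89 higher and 18 lower (camera adjusted p = 0.974). PLEOSDRAFT_1032080 fell from 799.9 ± 347 to 238 ± 53.3 FPKM (-1.65 ± 0.324, adjusted p = 0.00695) and PLEOSDRAFT_33357 from 3.99 ± 1.39 to 0.392 ± 0.126 FPKM (-3.20 ± 0.385), whereas PLEOSDRAFT_50083 rose from 24.9 ± 7.58 to 148 ± 14.9 FPKM (2.68 ± 0.194) and PLEOSDRAFT_49924 from 50.1 ± 9.46 to 173 ± 23.6 FPKM (1.89 ± 0.194). Of the 3 CYP51 copies, PLEOSDRAFT_1035254 fell from 305 ± 87.2 to 79.1 ± 11.3 FPKM (-1.84 ± 0.203, adjusted p = 0.000321), PLEOSDRAFT_1061968 rose from 28.8 ± 3.58 to 57.7 ± 0.128 FPKM (1.11 ± 0.121, adjusted p = 0.000311), and PLEOSDRAFT_1047295 was not called (-0.30 ± 0.187). Of 7 genes annotated as P450 fused to its NADPH reductase 2 rose and 0 fell, PLEOSDRAFT_1052853 (0.70 ± 0.1) and PLEOSDRAFT_1074478 (0.54 ± 0.167), whereas 1 rose and 1 fell with library size as the sole scaling and on the TPM scale. The second call was lost without control replicate 2 (adjusted p = 0.0538), BBP replicate 1 (0.129) or 3 (0.115), or PB replicate 1 (0.15) or 3 (0.131), and the list was not called (camera adjusted p = 0.577). Of 32 ABC transporter genes 7 rose and 3 fell (adjusted p = 0.00258; adjusted p = 0.16 with an estimated correlation). Of 12 glutathione transferases 1 rose and 2 fell (adjusted p = 0.411), and 1 rose and 4 fell with library size as the sole scaling, on the TPM scale, under quantile scaling and with limma on log2(FPKM + 1). PLEOSDRAFT_1055238 fell to 15.8 ± 3.97 FPKM (-2.58 ± 0.404).

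Ribosomal protein genes were called higher with PB as a list. Of 149 structural genes of the ribosome 50 rose and 2 fell, with a median log2 change of 0.33 (camera adjusted p = 8.14e-05; adjusted p = 0.713 with an estimated correlation). In the KEGG ribosome pathway 50 of 113 rose and 0 fell (adjusted p = 5.59e-07; adjusted p = 0.971 with an estimated correlation). A member that rose, PLEOSDRAFT_1103034 (0.67 ± 0.192), carries the orthology number of a peroxisomal carrier. In central carbon metabolism 20 of 57 glycolysis and gluconeogenesis genes rose and 6 fell (adjusted p = 0.00155; adjusted p = 0.508 with an estimated correlation), 16 of 49 fatty acid degradation genes rose and 3 fell (adjusted p = 0.00378; adjusted p = 0.255 with an estimated correlation), and 13 of 37 tricarboxylic acid cycle genes rose and 1 fell (adjusted p = 0.0468; adjusted p = 0.565 with an estimated correlation). The last call was lost without control replicate 3 (adjusted p = 0.0724), BBP replicate 2 (adjusted p = 0.0629), BBP replicate 3 (adjusted p = 0.101) or PB replicate 1 (adjusted p = 0.0865), and with library size as the sole scaling 5 of its genes rose and 4 fell. With that scaling 12 glycolysis and gluconeogenesis genes rose and 8 fell, and 10 fatty acid degradation genes rose and 4 fell. The aldehyde dehydrogenase PLEOSDRAFT_1108860 (EC 1.2.1.3) rose from 25.7 ± 14.6 to 112 ± 10.2 FPKM (2.23 ± 0.321). Formate dehydrogenase PLEOSDRAFT_1071241 rose from 463 ± 5.39 to 1705 ± 104 FPKM (1.99 ± 0.319).

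Of 15 hydrophobin genes 2 rose and 7 fell, or 2 and 8 adjusted over the list alone (median -0.59, camera adjusted p = 0.0109; adjusted p = 0.244 with an estimated correlation). On log2(FPKM + 1) values the list was not called (camera adjusted p = 0.175). PLEOSDRAFT_163649 had no count in the 3 libraries with PB and was at least 56.5-fold lower than with BBP alone, taking a floor of 3 counts per library. Without BBP replicate 1 this bound was 44.6-fold. PLEOSDRAFT_1060612 fell from 178 ± 64.5 to 14.6 ± 4.48 FPKM (-3.51 ± 0.353), and hydrophobin 3, PLEOSDRAFT_1114379, from 12.4 ± 1.39 to 2.06 ± 0.596 FPKM (-2.46 ± 0.385). The 2 that rose, PLEOSDRAFT_160070 (1.58 ± 0.283) and PLEOSDRAFT_156845 (0.97 ± 0.288), were named after their values were seen. Of 209 carbohydrate-active genes 10 rose and 28 fell, or 10 and 27 adjusted over the list alone (camera adjusted p = 0.242), including a glycoside hydrolase family 16 gene, PLEOSDRAFT_1072937 (-4.14 ± 0.671), and a family 79 gene, PLEOSDRAFT_1059085 (-2.96 ± 0.221). The secreted-type peptidase gene PLEOSDRAFT_1088548 fell from 137 ± 58.1 to 11.8 ± 1.56 FPKM (-3.43 ± 0.422).

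Of 10 laccase genes 2 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.867, direction higher, against a median of -0.26). Laccases are copper oxidases of phenols, and PLEOSDRAFT_1089723 rose from 187 ± 61.8 to 1398 ± 216 FPKM (3.01 ± 0.636, adjusted p = 0.00955) and PLEOSDRAFT_51622 from 3.14 ± 0.155 to 18.5 ± 2.28 FPKM (2.66 ± 0.276). Of 11 peroxidases 0 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.427). They were a DyP-type peroxidase, PLEOSDRAFT_62271 (-1.76 ± 0.352), and a putative versatile peroxidase, PLEOSDRAFT_1089895 (-3.03 ± 0.779). The second call was lost without BBP replicate 1 (adjusted p = 0.0632) or 3 (0.0703) or without PB replicate 1 (0.0876), 2 (0.051) or 3 (0.0834). Of 28 esterases and lipases 5 rose and 4 fell, or 8 and 4 adjusted over the list alone (camera adjusted p = 0.357). In the esterase list 2 carbohydrate esterase family 4 genes went opposite ways, PLEOSDRAFT_1113735 up (1.87 ± 0.196) and PLEOSDRAFT_175606 down (-1.97 ± 0.136). The plant-expansin-like gene PLEOSDRAFT_1045423 rose from 19.6 ± 2.16 to 83.8 ± 8.58 FPKM (2.19 ± 0.362). None of the 39 oxidative phosphorylation genes or the 6 mating type genes was called by edgeR, over all genes or adjusted over the list alone (camera adjusted p = 0.472 and 0.427), while 1 oxidative phosphorylation gene fell with library size as the sole scaling and 2 fell on the TPM scale. In the wider KEGG oxidative phosphorylation pathway 3 of 86 genes rose and 1 fell, or 3 and 3 with library size as the sole scaling.

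In all, 1921 genes differed between BBP with PB and BBP alone, 938 higher and 983 lower. Of these, 311 and 465 changed by at least 1 log2 unit. In 45.3% of tested genes the FPKM values did not overlap, where libraries alike in scaling too would give 10%. Part of this excess may also come from scaling. With library size as the sole scaling the split was 621 higher and 1327 lower, the median over all genes moved by -0.11, and 22 ribosomal genes rose instead of 50, with a median of 0.215 in place of 0.325. Without 1 library the count fell to 1051 (PB replicate 3), 1106 (BBP replicate 1), 1135 (PB replicate 1) or 1148 (PB replicate 2).

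**Figure D3:**
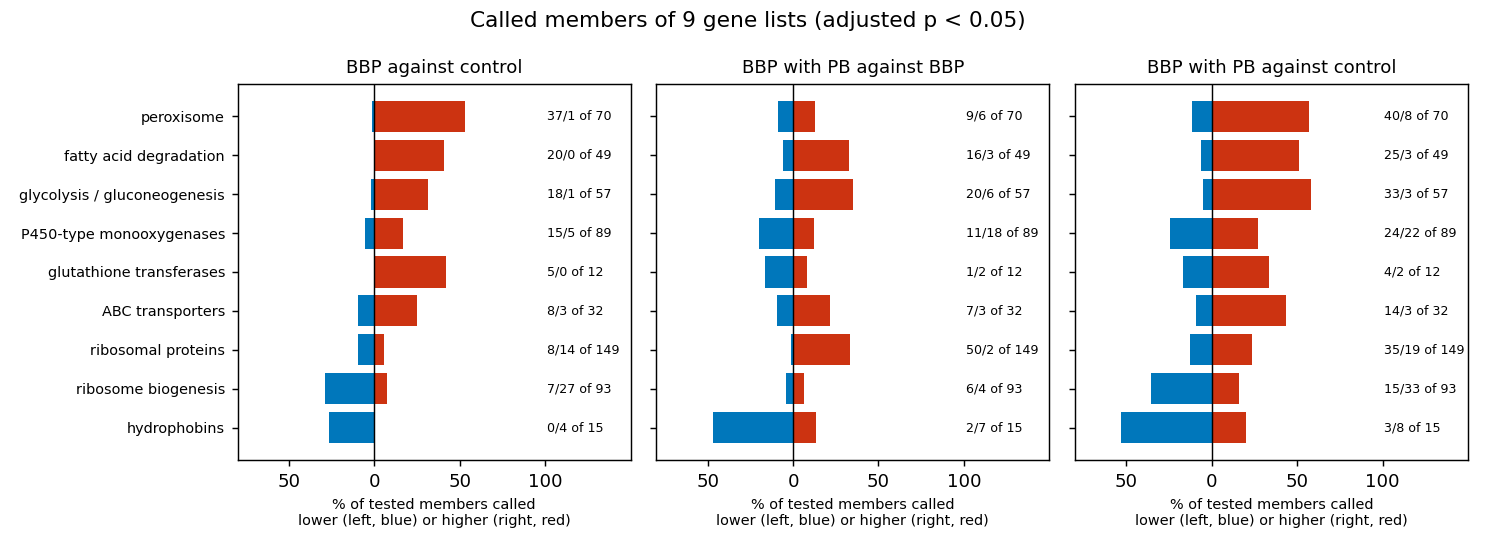
Percent of the tested members of 9 gene lists called lower (blue, left of 0) or higher (red, right of 0) at an adjusted p under 0.05 in the 3 comparisons, with the counts printed as higher/lower of tested. With BBP 37 of 70 peroxisome genes are higher, with PB against BBP 50 of 149 ribosomal protein genes (22 with library size as the sole scaling), and 8 of 15 hydrophobin genes are lower with BBP and PB than in control, where 3 are higher. With library size as the sole scaling the ribosomal counts against control turn from 35 higher and 19 lower to 12 and 43.

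The comparison of BBP with PB against control gave the joint change. The alcohol oxidase gene PLEOSDRAFT_1110004 was higher by 12.09 ± 0.578 log2 units (adjusted p = 8.97e-07), the alcohol dehydrogenase gene PLEOSDRAFT_1052916 by 5.97 ± 0.354 (3.69 ± 0.428 against 200.4 ± 2.7 FPKM), and the ABC transporter genes PLEOSDRAFT_1035372 and PLEOSDRAFT_1056093 by 4.97 ± 0.195 and 4.71 ± 0.173. The P450-type genes PLEOSDRAFT_49924 (4.36 ± 0.216) and PLEOSDRAFT_50083 (3.83 ± 0.204) rose, and so did phenylalanine ammonia-lyase, PLEOSDRAFT_173727, from 26.3 ± 1.43 to 378 ± 69 FPKM (4.05 ± 0.409), and the laccase PLEOSDRAFT_1089723, from 102 ± 88.7 to 1398 ± 216 FPKM (3.92 ± 0.663, and 4.97 without control replicate 1). Vmh2, PLEOSDRAFT_1091049, fell (-10.34 ± 1.02, adjusted p = 6.45e-05), as did the family 16 glycoside hydrolase PLEOSDRAFT_1072937 (-6.39 ± 0.742) and the versatile peroxidase PLEOSDRAFT_1089895 (-5.03 ± 0.831). Without PB replicate 1 the change of Vmh2 was -11.14. The hydrophobin PLEOSDRAFT_163649 was at least 277-fold lower, and at least 178-fold without control replicate 3.

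Fatty acid degradation (25 higher and 3 lower of 49, adjusted p = 4.41e-08; adjusted p = 0.085 with an estimated correlation), the peroxisome (40 and 8 of 70, adjusted p = 5.29e-07; adjusted p = 0.166 with an estimated correlation) and glycolysis and gluconeogenesis (33 and 3 of 57, adjusted p = 1.66e-06; adjusted p = 0.32 with an estimated correlation) were called higher. So were ABC transporters (14 and 3 of 32, adjusted p = 0.00073; adjusted p = 0.085 with an estimated correlation), monooxygenase activity (14 and 8 of 40, adjusted p = 0.00156; adjusted p = 0.085 with an estimated correlation), aldehyde dehydrogenases (11 and 1 of 21, adjusted p = 0.00746; adjusted p = 0.411 with an estimated correlation) and the tricarboxylic acid cycle (15 and 2 of 37, adjusted p = 0.0283; adjusted p = 0.508 with an estimated correlation). With library size as the sole scaling the tricarboxylic acid cycle had 11 higher and 7 lower, with a median of 0.08 in place of 0.30, monooxygenase activity had 13 and 11, and the ABC median was -0.08 in place of 0.13. Glycolysis and gluconeogenesis then had 26 higher and 8 lower, with a median of 0.29 in place of 0.50, and the medians of fatty acid degradation, the peroxisome and aldehyde dehydrogenases were 0.395, 0.411 and 0.305 in place of 0.617, 0.635 and 0.523. P450-type genes went both ways, 24 higher and 22 lower of 89 (adjusted p = 0.3), and 17 higher and 31 lower with library size as the sole scaling. Of 3 CYP51 copies PLEOSDRAFT_1035254 fell (-0.94 ± 0.198), PLEOSDRAFT_1061968 rose (1.42 ± 0.122) and PLEOSDRAFT_1047295 was not called (-0.33 ± 0.187). The small-subunit processome was again called lower, with 27 of 40 genes down and 3 up (adjusted p = 0.000838; adjusted p = 0.997 with an estimated correlation), while 35 ribosomal structural genes were higher and 19 lower (adjusted p = 0.319).

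Of 15 hydrophobin genes 3 rose and 8 fell, or 3 and 9 adjusted over the list alone (median -1.01, camera adjusted p = 0.0417; adjusted p = 0.421 with an estimated correlation). The list call was lost on log2(FPKM + 1) values (camera adjusted p = 0.388), without BBP replicate 3 (adjusted p = 0.0506) and without PB replicate 1 (adjusted p = 0.0666). Of 10 laccases 3 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.643), and the third that rose was the laccase small subunit PLEOSDRAFT_1067572 (2.37 ± 0.492). Of 11 peroxidases 1 rose and 3 fell, or 2 and 3 adjusted over the list alone (camera adjusted p = 0.427), and 0 rose and 3 fell with library size as the sole scaling. Of 28 esterases 11 rose and 5 fell, or 11 and 6 adjusted over the list alone (camera adjusted p = 0.183). Of 209 carbohydrate-active genes 39 rose and 42 fell, or 39 and 41 adjusted over the list alone (camera adjusted p = 0.643), and 21 rose and 61 fell with library size as the sole scaling. Of 39 oxidative phosphorylation genes 1 rose and 2 fell, or 0 and 0 adjusted over the list alone (camera adjusted p = 0.75), and 0 rose while 11 fell with library size as the sole scaling, 12 on the TPM scale and 17 under quantile scaling. In the wider KEGG oxidative phosphorylation pathway 10 of 86 genes rose and 9 fell, or 3 and 16 with library size as the sole scaling. Of 6 mating type genes 2 pheromone receptors rose, PLEOSDRAFT_1021555 (0.83 ± 0.262) and PLEOSDRAFT_1079000 (0.49 ± 0.144), with the same counts adjusted over the list alone (camera adjusted p = 0.319). On the TPM scale, with library size as the sole scaling and with limma on log2(FPKM + 1) 0 of the 6 were called, and under quantile scaling 3 mating type genes rose. The first call was lost without control replicate 1 (adjusted p = 0.0758), 2 (0.0522) or 3 (0.0535) or PB replicate 2 (0.103) or 3 (0.0665), and the second without control replicate 1 (0.0554) or 2 (0.0565) or PB replicate 1 (0.087).

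In all, 3865 genes differed between BBP with PB and control, 1871 higher and 1994 lower. Of these, 770 and 786 changed by at least 1 log2 unit. In 57.2% of tested genes the FPKM values did not overlap, where libraries alike in scaling too would give 10%. Here too part of the excess may come from scaling. With library size as the sole scaling the split was 1196 higher and 3183 lower, and the median over all genes moved by -0.22.

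The design also asked whether PB reversed the response to BBP. Most genes that rose with BBP stayed up when PB was added: of 947, 602 were not called between BBP with PB and BBP, 234 rose further and 111 fell. Of the 602, 503 were still higher than control. Of the 783 genes that fell with BBP, 619 were not called, 92 fell further and 72 rose, and 481 of the 619 were still lower than control. Among the 111 that rose and then fell were the P450-type genes PLEOSDRAFT_1032080 and PLEOSDRAFT_1047061 (-1.46 ± 0.317 with PB), both still above control (3.50 ± 0.349 and 2.23 ± 0.337), CYP51 PLEOSDRAFT_1035254, and PLEOSDRAFT_1063268 (EC 6.4.1.4, methylcrotonoyl-CoA carboxylase of leucine breakdown). The last went from 5.3 ± 1.26 FPKM in control to 44.3 ± 24 with BBP (3.15 ± 0.428) and 4.32 ± 1.33 with PB (-3.26 ± 0.432). The expansin-like gene PLEOSDRAFT_1045423 fell with BBP and rose back with PB. Independent lists would share 94.51 genes up in both, 81.89 down in both, 99.04 up then down and 78.14 down then up. In 20 simulations of unchanged groups all 9 libraries were drawn anew around the mean of the BBP group. No measured library was kept, and both comparisons shared the simulated BBP group. At most 1 gene per direction was called in each simulation, so their 0 shared genes are no reference for these counts. Across genes, which are not independent replicates, the correlation of the 2 log2 changes was 0.12, against -0.502 in those simulations, and the covariance was 0.05056 against -0.0357. The shared BBP libraries push both values down. Where no gene changes, a shared group of equal size sets the -0.502 by itself. That correlation is therefore no reference for groups in which many genes changed. The count of genes that went opposite ways, 183, was 91 without control replicate 2, 98 and 113 without BBP replicate 1 and 3, and 92, 89 and 93 without PB replicate 1, 2 and 3. The count that went the same way, 326, was 184 without BBP replicate 1, 197 without control replicate 2 and 198 without PB replicate 2, and 407 without control replicate 3.

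Against control, 751 genes were higher in both treatments and 575 lower in both, 1326 in all, 20 rose and then fell below control, and 11 fell and then rose above it. Independent lists would share 188.5 and 166.1 in the same direction and 200.9 and 155.9 in opposite directions. In 20 simulations of unchanged groups all 9 libraries were drawn anew around the mean of the control group. No measured control was kept, and both comparisons shared the simulated controls. These simulations had at most 2 called genes per direction and shared at most 1, which is no reference for these counts. The correlation of the log2 changes across genes was 0.683, against 0.496 in the simulations. Where no gene changes, a shared control group of equal size sets the 0.496 by itself, so it is no reference for the 0.683. The covariance was 0.3905, against a mean of 0.0351 in the simulations. The 3 controls cannot be split into parts of at least 2 libraries, so part of the excess over independent lists may come from the shared controls. In the simulations sharing alone gave a covariance of 0.0304 to 0.0403, which argues against it as the source of most of the 0.3905. That range rests on the simulated spread, with genes drawn independently. Without control replicate 2 the count in the same direction was 772.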

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

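Chosen only after the result was seen were limma on log2(FPKM + 1), DESeq2, scaling by library size alone, camera on log2(FPKM + 1) and the fit without both BBP replicate 2 and control replicate 3. Of 250 called results of named genes, each in the comparison that named it, 0 changed sign in the alternatives, which were not run for other calls given in the text. No list call changed its camera direction in the alternatives run for lists, which did not include scaling by library size. By library size alone the split in BBP against control turned from 947 higher and 783 lower to 684 and 1108, that of the ribosomal genes in BBP with PB against control from 35 and 19 to 12 and 43, and the ABC transporter median there from 0.13 to -0.08. Of the 250, 170 kept their call under every alternative in which their gene was tested (219 were tested at a mean FPKM of at least 5), while 0 of 27 list calls did, since an estimated correlation ended each of them. With that correlation camera called 0 lists, against 13, 6 and 8 in BBP against control, BBP with PB against BBP and BBP with PB against control (7, 3 and 5 of 41 at an unadjusted p under 0.05). It called 0 ontology terms, against 56, 7 and 22 of 480 (35, 5 and 17 unadjusted), and 0 KEGG pathways, against 28, 9 and 16 of 99 (16, 7 and 17 unadjusted). Counts that moved by over 1.5 times follow, and the cause was not tested except where fewer libraries or a stricter threshold make it so. With limma on log2(FPKM + 0.1), BBP with PB against control gave 1246 higher and 3063 lower, and with limma on log2(FPKM + 1) 3061 lower. On the TPM scale BBP with PB against BBP gave 620 higher and BBP with PB against control 1196 higher and 3247 lower, and by library size alone these were 621, 1196 and 3183. From its own 6 libraries BBP against control gave 879 genes, 515 higher and 364 lower. Quality weights gave 3499 genes for BBP with PB against BBP, 1761 higher and 1738 lower, with 418 going opposite ways to the BBP response and 622 the same way. DESeq2 gave 313 opposite. Without both BBP replicate 2 and control replicate 3, BBP with PB against BBP gave 2971 genes, 1499 higher, and 379 opposite. At a change of at least 1 log2 unit the 3 comparisons gave 543 (320 higher, 223 lower), 776 (311, 465) and 1556 (770, 786), with 407 shared against control, 36 opposite and 99 the same way. At an adjusted p under 0.01 they gave 626 (418, 208), 836 (433, 403) and 2359 (1215, 1144), with 522, 38 and 111. Leaving out 1 library gave 967 to 1854 genes for BBP against control (584 to 942 higher, 383 to 912 lower), 1051 to 2461 for BBP with PB against BBP (515 to 1268, 536 to 1193) and 2877 to 4169 for BBP with PB against control (1449 to 2004, 1428 to 2165). It gave 772 to 1435 shared against control, 89 to 258 opposite, 184 to 407 the same way, and 8 to 14, 5 to 7 and 7 to 8 lists. Replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at -0.152 to 0.206, and 0 libraries correlated best with their own number in both other groups. With the replicate number as a replicate block the counts were 1396, 1568 and 3612, within 1.5 times of the values without it, and 3 list calls were lost, those of ribosome biogenesis (adjusted p = 0.0562) and transmembrane transporters (adjusted p = 0.0502) in BBP against control and of the tricarboxylic acid cycle (adjusted p = 0.0502) in BBP with PB against BBP. The block gained 3, P450-type genes (adjusted p = 0.0485) and GMC-type oxidoreductases (adjusted p = 0.0483), both higher, in BBP against control and DNA replication, higher, in BBP with PB against BBP (adjusted p = 0.0374). With camera on log2(FPKM + 0.1) the calls of ABC transporters (adjusted p = 0.0833) and ribosome biogenesis (adjusted p = 0.0611) in BBP against control and of hydrophobins in both comparisons with PB (adjusted p = 0.129 and 0.372) were lost. It gained 3, cell wall organization (adjusted p = 0.0208) and oxidative phosphorylation (adjusted p = 0.0175), both lower, in BBP against control and DNA replication, higher, in BBP with PB against BBP (adjusted p = 0.0169), and camera on log2(FPKM + 1) gained the same lists (adjusted p = 0.0209, 0.0196 and 0.0196). Depth limits the low genes, where 3 counts equal 0.061 to 0.0787 CPM by total count. After TMM scaling the mean of this floor over the libraries with PB was 0.0811 CPM, which was used for the fold bounds of PLEOSDRAFT_163649.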

Other observations

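The tests of a single BBP library, of reads shared between related genes and of PB acting without BBP were chosen only after the result was seen. Amino acid breakdown pathways, not described so far, were higher with BBP and PB than in control, by camera over 99 KEGG pathways. In tyrosine metabolism 20 of 34 genes rose and 3 fell (median log2 change 0.72, adjusted p = 1.95e-05; adjusted p = 0.0987 with an estimated correlation), in valine, leucine and isoleucine degradation 28 of 51 rose and 3 fell (adjusted p = 2.09e-05; adjusted p = 0.28 with an estimated correlation), in lysine degradation 18 of 37 rose and 2 fell (adjusted p = 0.000135; adjusted p = 0.141 with an estimated correlation), and in beta-alanine metabolism 17 of 36 rose and 2 fell (adjusted p = 0.000165; adjusted p = 0.0987 with an estimated correlation). These pathways share members, such as the aldehyde dehydrogenase PLEOSDRAFT_1108860. With BBP alone 14 of 51 genes of valine, leucine and isoleucine degradation rose and 0 fell (adjusted p = 0.000419, or 0.331 with an estimated correlation). Tyrosine metabolism (9 rose and 1 fell of 34, adjusted p = 0.00736, or 0.169) was also called higher. So was tryptophan metabolism (21 and 1 of 56, adjusted p = 0.000234, or 0.169), also with BBP and PB against control (24 and 4, adjusted p = 1.95e-05, or 0.0987). None of these pathways was recounted by library size alone, which moved the median over all genes by -0.22 in BBP with PB against control.

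Ribosomal protein genes were called higher as a list with PB than with BBP alone, 50 of 149 rising and 2 falling, with a median log2 change of 0.325 (adjusted p = 0.713 with an estimated correlation). For 10000 lists matched on length and expression the medians centred on 0.0397, with a 95th percentile of 0.0996, and 0.325 lay at percentile 100. This argues against transcript length as the source. The matched genes were drawn independently, so these medians spread less than those of co-regulated genes would. How close the matches came was not checked. Leaving out BBP replicate 1, 2 or 3 gave medians of 0.37, 0.299 and 0.249, each with the list still called at the preset correlation (adjusted p = 4.39e-06, 0.000178 and 0.00292), so no single BBP library set that median. Under 5 other scalings the lowest median was 0.198. A biological response to PB, or to PB with BBP, may remain as a hypothesis, and it stays untested without PB alone.

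With BBP and PB 8 of 15 hydrophobin genes were lower than in control and 3 higher, and the list call was lost with an estimated correlation (adjusted p = 0.421) and on log2(FPKM + 1) values (adjusted p = 0.388). Reads moving between related genes would leave their sum in place, but the summed CPM of all hydrophobin genes fell from 893.3 ± 250 in control to 273.9 ± 46.4 with BBP and 62.16 ± 3.13 with BBP and PB (SD, n = 3), a ratio of 0.0696. Such a sum follows abundant genes such as Vmh2 and PLEOSDRAFT_1060612, so it cannot decide the question for the less abundant members. Reads passing to genes not described as hydrophobins lie outside it. All 8 genes called lower stayed called lower under each of 5 other scalings. The TPM scale, library size alone and log2(FPKM + 1) moved changes in this comparison down (median shift -0.224, -0.218 and -0.195), which favours lower calls. Median-of-ratios and quantile scaling moved them up by only 0.0119 and 0.0352. These scalings are therefore a weak test of whether scaling made the falls. PB acting without BBP cannot be told apart from a joint effect, since 0 libraries held PB alone.

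The alcohol oxidase PLEOSDRAFT_1110004 and formate dehydrogenase PLEOSDRAFT_1071241 rose together with BBP and PB, and a hypothesis is that methanol or formaldehyde oxidation may be raised. A step between them was tested: the gene PLEOSDRAFT_1063808, of the glutathione-dependent formaldehyde dehydrogenase class, rose from 216 ± 41.4 to 651 ± 88.4 FPKM (log2 change 1.79 ± 0.242, edgeR adjusted p = 0.00037), which is in line with it, although 1871 of 9399 tested genes rose in this comparison. Reads moving between the 4 alcohol oxidase genes are argued against by their summed CPM, 288.3 ± 67.5 in control and 3099 ± 341 with BBP and PB, a ratio of 10.75. PLEOSDRAFT_1054127 (EC 3.1.2.12), of the step that follows, rose too (1.33 ± 0.107). It was already called higher with BBP alone (1.01 ± 0.107, edgeR adjusted p = 0.000489). Its change with PB against BBP was not called (0.32 ± 0.106, adjusted p = 0.0576). PLEOSDRAFT_1063808, which also carries EC 1.1.1.1, was called higher both with BBP alone (0.97 ± 0.237, adjusted p = 0.0206) and with PB against BBP (0.82 ± 0.236, adjusted p = 0.036). Of the 4 alcohol oxidases PLEOSDRAFT_1109402 fell (-2.13 ± 0.351), while PLEOSDRAFT_1067243 (0.38 ± 0.374) and PLEOSDRAFT_1113777 (-0.20 ± 0.241) were not called. These alcohol oxidases were named after their values were seen. Thus only 1 of the 4 rose, and not every gene of these steps did. Neither methanol nor formaldehyde was measured here.

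For each comparison the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. The real splits gave 1730, 1921 and 3865 called genes and the highest other split gave 0 by edgeR in each, with up to 818, 701 and 716 genes at an unadjusted p under 0.05. Only 1 split, the real one, gave as many in each comparison. Each other split mixes libraries of both groups, so the group difference enters the spread within its parts. The counts of those splits are therefore no reference for chance.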
